A study of Escherichia coli with 13 samples.

How the data were processed

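Dimethyl sulfate (DMS) methylates the Watson-Crick face of unpaired and accessible adenosines and cytidines, and reverse transcriptase reads the adducts as mutations, so the mutation rate per nucleotide reports how open an A or C site is. The assay was applied to ribosomal RNA of Escherichia coli MRE600, a strain often used for ribosome work because of its low ribonuclease content, in 13 libraries. Newly made RNA was marked with 4-thiouridine (4U), a uridine analogue that can be biotinylated and pulled down, and rifampicin, which stops transcription initiation, started the chase. Per the labels, cells were labelled at 0.5 mM 4U, and nascent samples then received rifampicin at 200 µg/mL for the stated chase time. For the labelled mature samples the labels disagree: the titles and the protocol give 10 min of 4U and the sample attributes give 1 min, and 1 of these libraries carries a DMS time of 31 s where the protocol gives 30 s.

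The values used were the mutation fractions per nucleotide that the authors deposited in a table of 4982 positions, with a column for each library. Per the submitters' processing notes, reads were handled with cutadapt and Bowtie2, without versions. Per the labels' protocols, RNA was fragmented with zinc ions, size selected, reverse transcribed with a thermostable group II intron enzyme, and amplified by PCR without any stated molecular identifiers. How mutations were called, which quality or depth filters were used and whether a background was subtracted was not given in the sources used here. The deposited fractions come with no read counts or coverage, so the depth behind each value is unknown, and no counting interval or floor was computed. An exact 0 can be a missing estimate or a true 0 and is reported only as a listing at 0. The labels place the libraries on 3 flow cells: both unlabelled mature controls on the first, a replicate of the 1.5 min chase alone on another, and the rest together. Flow cell therefore cannot be told apart from labelling in the unlabelled controls. No genome build applied to the table, so positions are given by the standard E. coli numbering within each RNA, found by matching the known end sequences of 16S (1542 nt), 23S (2904 nt) and 5S (120 nt) rRNA. The reference sequences also carry leader, spacer and trailer segments outside the mature ends. Each rate pools all rRNA operon copies.

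From these fractions, the A and C sites of the mature RNAs were kept for the comparisons of DMS rates (2203 sites). A total of 11 A or C sites with known modifications and 28 sites with a rate over 2% in any library without DMS were left out, which left 2164 sites. Rates were divided by a factor per library, the mean of the rates between the 90th and 98th percentiles of the 16S and 23S sites, set to a geometric mean of 1. The tests were made with limma 3.58.1 in R 4.3.3 (eBayes with a trend) on log2(scaled rate + 0.001), with the Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale and understate changes at low rates. The main contrast set the mean of the nascent groups at 0.5, 1, 1.5 and 2.5 min (5 libraries) against the 2 labelled mature libraries. Further contrasts set each chase time against mature, tested a linear change over chase time, and compared labelled with unlabelled mature ribosomes. Only the labelled mature and the 1.5 min groups had 2 libraries, so the fit had 2 residual degrees of freedom. The other nascent groups were assumed to vary like these. Nothing in the labels says that replicates came from separate cultures. The p-values of single sites therefore measure only the spread between these libraries, which may be technical. No groups of 3 or more libraries each were compared in that fit.

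Response to DMS was fitted over all 13 libraries on unscaled rates with the stage (unlabelled mature, labelled mature, nascent) as a covariate, at the same 2164 sites. A set of 28 lists of sites was tested with camera at a preset correlation of 0.01 and with an estimated correlation. At the preset correlation its p-values rest on the spread over sites, not between libraries, so small values are no evidence over libraries. It held 11 domain lists (the domains of 16S and 23S, and 5S) and 17 functional lists, such as the decoding site or helix 69. Sites were also classed by the unlabelled mature DMS library as closed (rate under 1%) or open (over 3%), a library that was not part of the fold changes. Among 36 known modified nucleotides, 12 with a change on the Watson-Crick face were compared over the 11 labelled libraries with DMS as a covariate, on unscaled log2 rates, and adjusted over that list and over all 16S and 23S positions. The named sites followed a fixed rule: the 12 face modifications; up to 12 higher and 12 lower sites with the largest called change whose rates (scaled, as in the fit) lay on that side in all 5 nascent libraries and averaged at least 1% in the higher group; up to 5 called sites per direction over chase time; 3 members of each called functional list; and the 5 highest A or C sites of labelled mature ribosomes. Lists, classes, tests, the rule and most alternatives were fixed before the data were examined. The rule as fixed did not say whether scaled or deposited rates decide the side. On the deposited rates all nascent libraries lay below both mature ones at 3 sites, so most of the named lower sites depend on the use of scaled rates. The lists and modified positions came from textbook knowledge of the E. coli ribosome.

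The fit was tested on simulated data built from the mature libraries at 2164 sites. At a log2 change of 2, 49 of 50 raised and 49 of 50 lowered sites were called; at a log2 change of 1, 13 of 50 raised and 14 of 50 lowered sites were. Of 1964 unchanged sites, 6 were called, and their median log2 estimate was -0.13. The simulated libraries had independent noise and no library-wide shift or added background, so these counts do not cover errors from such shifts. For the lists, a shifted list of 40 sites was found, and 5 of 200 unshifted lists had an unadjusted p under 0.05. Alternatives covered the pseudocount, the scaling, the filters, the variance trend, subtraction of the rate without DMS, the choice of mature libraries, base, flow cell and each library left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.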

Results

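Mutation rates of E. coli ribosomal RNA were measured in 13 libraries, 8 from DMS-treated cells and 5 from cells without DMS. Unlabelled mature ribosomes gave 1 library with and 1 without DMS. Mature ribosomes labelled with 4-thiouridine gave 2 libraries with DMS and 1 without. Nascent ribosomes gave 5 DMS libraries, 1 each at 0.5, 1 and 2.5 min of rifampicin chase and 2 at 1.5 min, and 3 libraries without DMS at 0.5, 6.5 and 10.5 min. The depth behind the rates is unknown. Groups with 1 library have no replicate error of their own.

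DMS raised the rates at A and C sites of 16S, 23S and 5S rRNA. Over all 13 libraries, 1945 of 2164 sites were higher with DMS (limma, Benjamini-Hochberg adjusted). Of these, 1156 were among the 1165 A sites and 789 among the 999 C sites, with median log2 changes of 1.91 and 0.77. In unlabelled mature ribosomes the median A rate was 0.0657% without DMS and 0.441% with it, and the median C rate moved from 0.246% to 0.384%. In labelled mature ribosomes the median A rate was 0.179% without DMS and 0.414% and 0.383% in the DMS replicates. The median C rate there was 0.366% without DMS and 0.482% and 0.437% with it. G and U sites were not part of this fit. In unlabelled ribosomes their medians also rose, from 0.2975% to 0.418% and from 0.0751% to 0.0957%. The labelled mature G median was 0.624% without DMS and 0.73% and 0.594% with it. At 0.5 min of chase, C had 0.369% without and 1.04% with DMS, G 0.653% and 1.57%, and U 0.173% and 0.43%. These medians do not show that the rise at C sites was specific to that base. Among the nascent chase times only 0.5 min had libraries both with and without DMS. The count of 1945 sites therefore also holds differences between early and late chase times. Among these 2164 sites, the highest rates in labelled mature ribosomes lay at 16S A915, next to the central pseudoknot, with 68.1% ± 1.04 (SD, n = 2), and at 16S A908 in helix 27. They were followed by 23S A340 (19.3%), 23S A1640 (18.2%) and 16S A432 (16.1%, means of 2).

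Nascent DMS libraries had higher rates than mature ones at all 4 bases in 4 of the 5 libraries. The median A rate was between 0.974% and 1.74% in the 5 nascent DMS libraries. The median C rate was between 0.659% and 1.23%, against 0.482% and 0.437% in labelled mature ribosomes. U, which was not counted as a DMS target here, was also higher, with medians between 0.43% and 0.966% against 0.19% and 0.165%. Whether DMS reacted with U under the conditions used was not tested, so the U rate may hold some DMS signal. G was higher in 4 of the 5 libraries (1.00% to 1.57%, against 0.73% and 0.594%), while the second 1.5 min library had 0.591%. In the nascent libraries without DMS, median U rates were 0.173%, 0.153% and 0.203%, beside 0.17% in the labelled mature library without DMS.

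**Figure D1:**
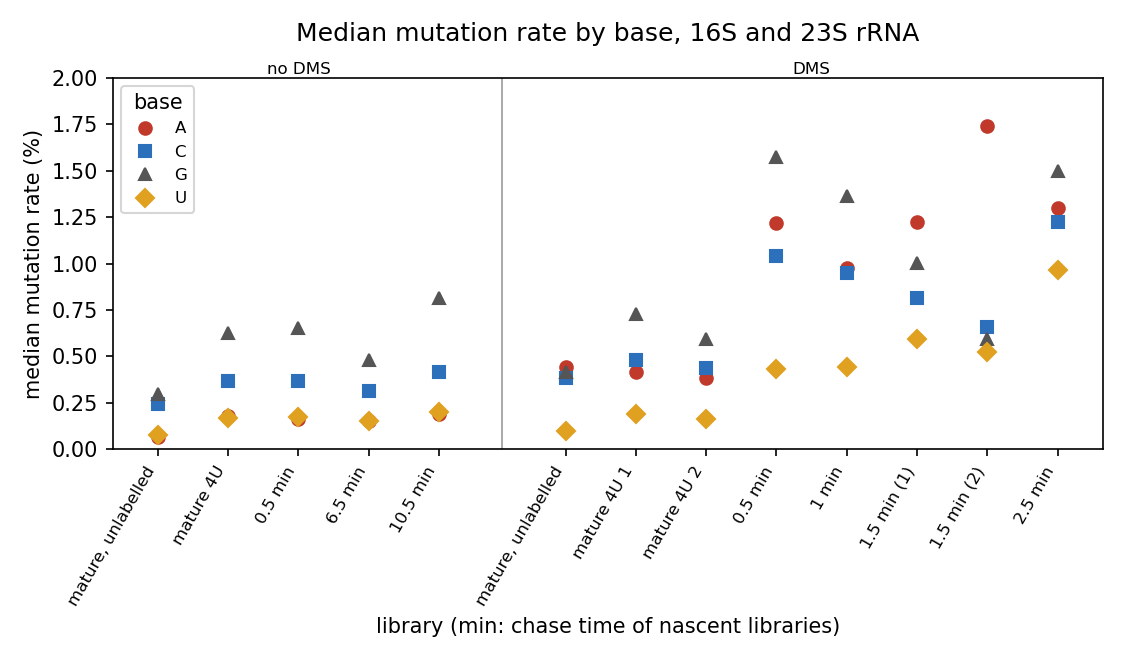
Median mutation rate (%) over 16S and 23S positions of each base (y axis) in each of the 13 libraries (x axis), without DMS on the left and with DMS on the right; each point is the median over the sites of that base in a library. The A medians of the 5 nascent DMS libraries lie between 0.974% and 1.74%, above the 0.414% and 0.383% of labelled mature ribosomes.

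The comparison of nascent with mature ribosomes asks where rRNA that is still being assembled is more or less accessible than in finished particles. Relative to the strongly reactive sites of each library, 397 sites were higher and 25 lower in nascent ribosomes among 2164 tested (limma, adjusted p under 0.05). Among A sites 342 were higher and 22 lower, and among C sites 55 were higher and 3 lower. Fitted by themselves, A sites gave 631 higher and 25 lower, and C sites 1 higher and 0 lower (limma, 151 C sites at an unadjusted p under 0.05). The higher sites were spread over the RNAs, with 148 in 16S, 245 in 23S and 4 in 5S, and the lower ones comprised 14 in 16S, 10 in 23S and 1 in 5S. The split depended on the scaling: without scaling 1637 sites were higher and 3 lower, and with median centring 37 were higher and 123 lower. The median log2 change over all sites was 0.56 with the scaling, 1.10 without and -0.07 with centring, so single sites are to be read against it. On the deposited rates, all 5 nascent libraries lay above both mature ones at 1678 sites (77.5%) and below both at 3. For a single site chance gives 4.76% each way. A shift of a whole library moves many sites at once, so this share is no test of changes at single sites. With either 1.5 min library left out, 14 sites were higher and 3 lower. Without the first or the second labelled mature library 9 and 11 were lower. After subtraction of each library's median U rate limma called 0 and 0, with scaling (274 sites at an unadjusted p under 0.05) and without (422), also with a pseudocount of 0.01 (259 and 370). It called 22 and 4 with that pseudocount and scaling when sites with a mean rate under 1% were also left out.

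Of the 12 higher sites named here, 3 passed with either 1.5 min library left out and 9 without the first labelled mature library. Without a variance trend 6 passed, with the rate of the labelled mature library without DMS subtracted 4, and after subtraction of the U rate at most 1. With that subtraction and scaling, 16S A1176 had a log2 change of 2.64 (SE 0.40, adjusted p = 0.301), 16S A872 of 2.55 (SE 0.48, 0.301) and 23S A160 of 2.48 (SE 0.52, 0.317), and with a pseudocount of 0.01 in addition 1.37, 0.60 and 0.66. The prior degrees of freedom of limma went from 13.25 to 2.36 with the subtraction. Of the 12 sites, 16S A1176 in the 3' major domain had 0.34% and 0.472% in the mature libraries. In nascent ribosomes it had between 1.89% and 4.07% (log2 change 2.15, SE 0.27, adjusted p = 0.000403). In the central domain, 16S A872 had a mature mean of 0.101% ± 0.0886 (SD, n = 2) and 1.54% ± 0.193 (n = 2) at 1.5 min, with a log2 change of 2.35 (SE 0.41, adjusted p = 0.00275). In domain I of 23S rRNA, 23S A160 had 0.132% ± 0.123 (n = 2) in mature and 2.20% ± 0.599 (n = 2) in 1.5 min ribosomes, a log2 change of 2.25 (SE 0.42, adjusted p = 0.00423). The other sites of this group were listed at 0 in at least 1 mature library, and no fold is given for them. Near the 3' end of 16S rRNA, A1502 at the base of the decoding helix and C1524 in helix 45 were listed at 0 in both mature libraries. Their nascent rates were between 0.935% and 2.40%, and between 0.938% and 2.45%. The unlabelled mature library had 0.781% and 0.49% there, and the highest rates without DMS were 0.148% and 1.29%. 5S C114 was likewise listed at 0 in both and had between 0.435% and 3.29% in nascent ribosomes, against at most 0.885% without DMS. With 0 in 1 mature library, 16S A171, A906, A1480 and A1513, 5S A94 and 23S C145 had nascent means of 1.23%, 1.06%, 1.11%, 1.30%, 1.18% and 1.06%.

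Of the 25 sites that were lower after scaling, 19 had over 3% in the unlabelled mature library. 16S A908 in helix 27, which packs against the decoding site, had 29.4% ± 5.52 (SD, n = 2) in labelled mature ribosomes and between 15.5% and 22.0% in nascent ones. Its log2 change was -1.30 (SE 0.17, adjusted p = 0.000403), and the unlabelled mature library had 17.0%. 16S A1408, a decoding-site base bound by aminoglycosides, had 10.2% ± 0.183 (n = 2) in mature ribosomes and between 6.74% and 11.7% in nascent ones (log2 change -0.99, SE 0.15, adjusted p = 0.00135). 16S A915 was between 51.2% and 66.7% in nascent ribosomes (log2 change -0.83, SE 0.12, adjusted p = 0.00065). These 3 sites were the ones also called lower without scaling, with log2 changes of -0.66, -0.35 and -0.19. 16S A782 had 7.60% ± 0.749 (n = 2) in mature ribosomes and 5.36% to 6.73% in nascent ones, but without scaling its adjusted p was 0.0843. At 16S A432, A759, C1469, A1531 and A1534, at 23S A1050 and C2254 (the latter in the P loop that binds the CCA end of P-site tRNA) and at 5S A109, log2 changes between -0.62 and -0.86 with scaling shrank to between -0.24 and 0.00 without it. 23S A1640 was lower with scaling (-0.52, adjusted p = 0.0216) but had a log2 change of 0.12 (adjusted p = 0.301) without it. 23S A340 had -0.07 (adjusted p = 0.726) with scaling and was higher without it (0.57, adjusted p = 1.34e-07). All 25 lower sites were also called lower with median centring. Of the 12 named ones, 5 passed with either labelled mature library left out and 3 with either 1.5 min library left out. With the rate of the labelled mature library without DMS subtracted 9 passed, without a variance trend 0, and with the median U rate subtracted 0, with and without scaling. At 16S A908, A1408 and A915 that subtraction left log2 changes of -1.20, -0.93 and -0.70 with scaling and -0.70, -0.44 and -0.20 without. With a pseudocount of 0.01 and a mean rate of at least 1% in addition to it and scaling, 4 of the 12 passed.

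**Figure D2:**
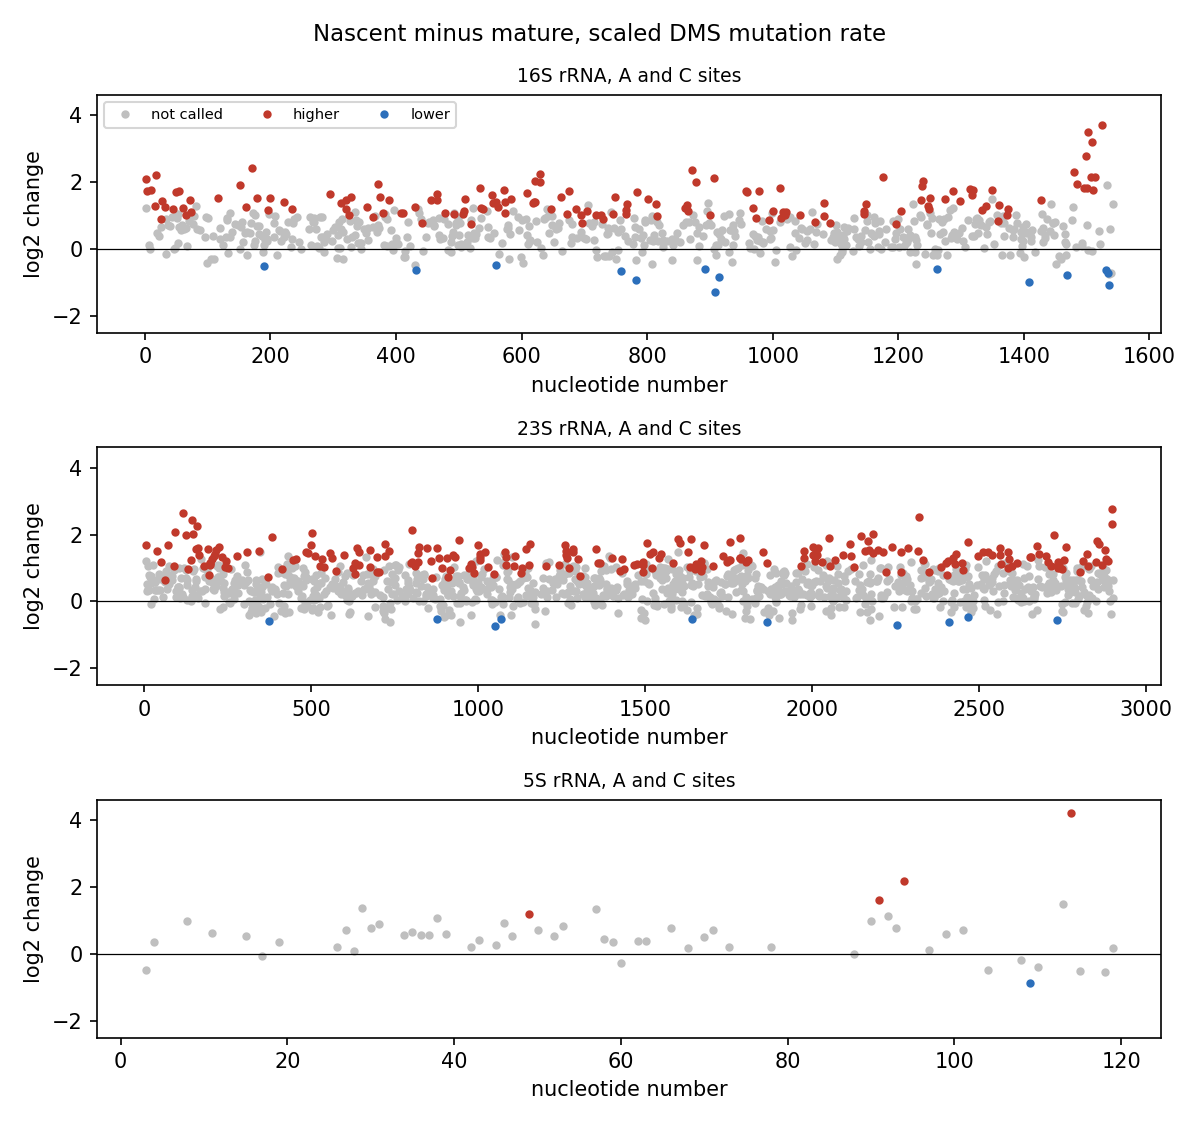
Log2 change of the scaled DMS mutation rate, nascent minus mature (y axis), against nucleotide number (x axis) for the A and C sites of 16S, 23S and 5S rRNA. Each point is a site, red for the 397 called higher, blue for the 25 called lower and grey for the rest; the median over all sites is 0.56.

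Sites that were protected in mature ribosomes had larger log2 changes than sites that were already open under each of the scalings of the deposited rates, but not with all of the background subtractions tried. Of 1849 sites that were closed in the unlabelled mature library, 369 were higher and 1 lower in nascent ribosomes, with a median log2 change of 0.63. Of 61 open sites, 2 were higher and 19 lower, with a median of -0.26. The deposited rates moved from a median of 0.384% to 0.999% at closed sites and from 5.74% to 7.02% at open ones. Both classes differed from the other sites (camera, adjusted p = 1.38e-29 for closed and 1.53e-34 for open sites; adjusted p = 0.00423 and 0.00465 with an estimated correlation). Without scaling the medians were 1.16 and 0.37, and with median centring 0.00 and -0.80, so the direction of change depended on the scaling. With the median U rate subtracted and no scaling the medians were 0.55 and 0.28, and the open class was no longer called (adjusted p = 0.313). With a pseudocount of 0.01 as well, the difference between the classes was -0.05 (camera, adjusted p = 0.925), beside 0.89 in the main fit. With scaling, that pseudocount alone gave a difference of 0.51 (camera, adjusted p = 1.51e-41). With scaling, that pseudocount and the U rate subtracted, it was 0.27 (camera, adjusted p = 1.00e-11).

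**Figure D3:**
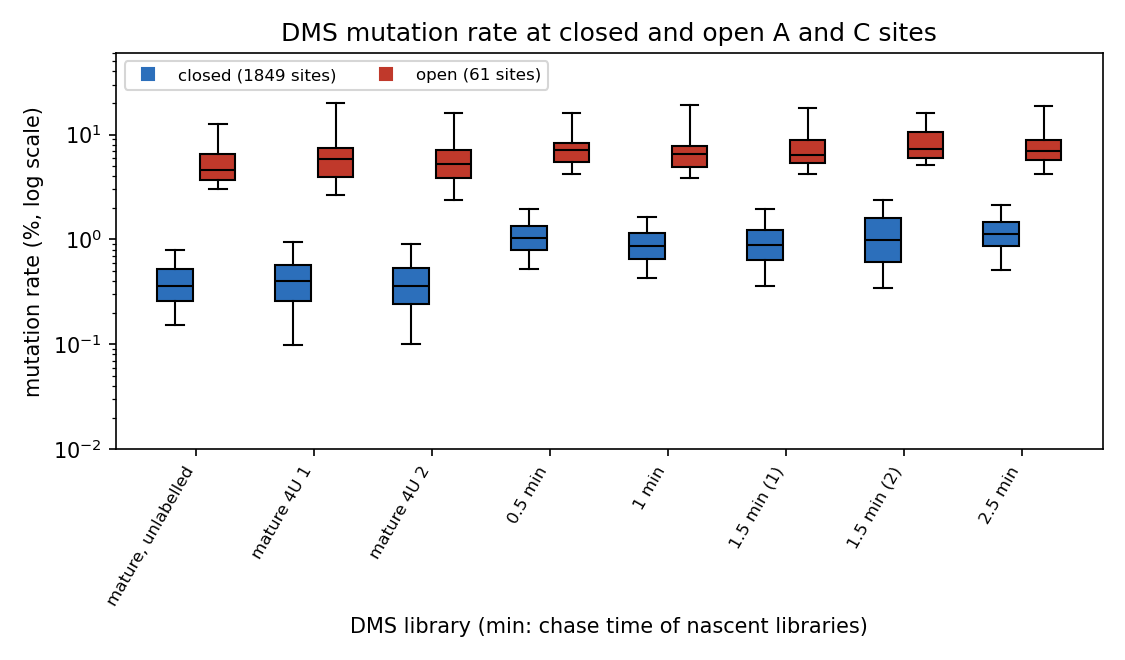
DMS mutation rate (%, log y axis) at 1849 closed and 61 open A and C sites in the 8 DMS libraries (x axis); boxes span the quartiles, the line is the median and whiskers run from the 5th to the 95th percentile of sites. Closed sites have higher medians in the 5 nascent libraries than in the mature ones, while the open classes overlap.

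Region by region, the rise was broad. The medians of the 11 domain lists lay between 0.49 (23S domain IV) and 0.65 (16S central domain). In 16S rRNA 55 of 266 sites of the 5' domain, 39 of 161 of the central, 42 of 235 of the 3' major and 12 of 65 of the 3' minor domain were higher. In 23S domains I to VI the counts were 49 of 280, 63 of 334, 29 of 185, 27 of 181, 49 of 267 and 28 of 132, and in 5S 4 of 58. Lower sites numbered 3, 4, 2 and 5 in these 16S domains. In the 23S domains they numbered 1, 3, 1, 1, 3 and 1, and in 5S 1. The single list that differed from the other sites was the 3' tail of 16S rRNA with the anti-Shine-Dalgarno sequence, which base-pairs with mRNA, where none of 8 sites was higher and 3 were lower (limma, 5 at an unadjusted p under 0.05; camera, adjusted p = 8.63e-06). Its median log2 change was -0.67 while its mean was 0.00. The adjusted p was 0.821 with an estimated correlation and 0.075 with median centring (camera), and the call also ended without the first labelled mature library. The list median relative to all sites, -1.23 in the main fit, was -1.15 with centring and -1.22 without that library. Its members with the largest changes were C1533 (0% and 2.48% in mature, 1.46% to 3.53% in nascent ribosomes), A1542 (2.82% and 0%, 1.24% to 3.33%) and C1535 (2.61% and 1.63%, 0.363% to 2.88%). Helix 45 of 16S rRNA, which carries the KsgA dimethylations, had 5 of 8 sites higher and a median of 1.95, but the list did not pass (camera, adjusted p = 0.71). In this helix C1524 was listed at 0 in both labelled mature libraries and A1513 in 1. These listings can be missing estimates, and they raise the log2 changes.

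The remaining functional lists did not pass either (27 lists in all, adjusted p from 0.327 to 0.969). In 16S rRNA, 4 of 8 sites of the central pseudoknot, 4 of 16 of the helix 18 loop, 4 of 8 of the helix 23 loop, 1 of 8 of the helix 24 loop, 2 of 14 of helix 27, 6 of 30 of the head helices h31 and h34 and 4 of 14 of the decoding site were higher. In 23S rRNA the counts were 11 of 52 in the A-site finger, 3 of 29 in the GTPase-associated centre, 10 of 42 in the L1 stalk, 5 of 23 in the peptidyl transferase ring and 2 of 8 in the sarcin-ricin loop. Lower sites numbered 2 in helix 27 and 1 each in the decoding site, the A-site finger, the GTPase-associated centre and the P loop. No member of helix 69 (13 sites), the P loop (4) or the A loop (6) was called higher by limma (3, 1 and 3 at an unadjusted p under 0.05). Adjusted over the list alone, 7 sites were called in helix 27, 7 in the helix 18 loop and 9 in the peptidyl transferase ring, and 0 in helix 69, the A loop and the GTPase-associated centre, which had 15 sites at an unadjusted p under 0.05.

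Taken by chase time, the same fit called 15 sites higher and 2 lower at 0.5 min, 11 and 1 at 1 min, 334 and 27 at 1.5 min, and 18 and 5 at 2.5 min. The 1.5 min group had 2 libraries and the other groups 1, so these counts are not comparable as sizes of effect. With the rate of the labelled mature library without DMS subtracted the called sites numbered 1, 0, 0 and 2, without a variance trend 0, 0, 100 and 0, and with the median U rate subtracted 0 at each time, while without scaling they numbered 922, 338, 1165 and 1284. The medians over all sites were 0.62, 0.51, 0.42 and 0.69, and the limma counts at an unadjusted p under 0.05 were 430, 277, 709 and 490. No site changed linearly with chase time after adjustment (limma, 0 called, 10 at an unadjusted p under 0.05). The smallest p-values belonged to 23S C1049 and A1439, which were chosen after their values were seen. C1049 had 3.13%, 3.06%, 4.07% and 6.25%, and 6.29% at 0.5, 1, 1.5 (2 libraries) and 2.5 min. A1439 had 2.22%, 2.02%, 3.64% and 4.39%, and 4.36%. As a list, helix 69 of 23S rRNA, a bridge to the small subunit, rose with chase time (camera, median 0.26 log2 units per min over 13 sites, adjusted p = 0.00579). The list of 5S rRNA fell (-0.10 per min over 58 sites, adjusted p = 0.0106). With an estimated correlation both had an adjusted p of 0.712, and without the 2.5 min library they had 0.472 and 0.794. With the median U rate subtracted and scaling both had 0.422. The list medians relative to all sites, 0.22 and -0.13 per min, were 0.41 and -0.19 with that subtraction and 0.32 and -0.13 without the 2.5 min library. Without the 0.5 min library helix 69 had 0.35 and an adjusted p of 0.298. The other 26 lists had adjusted p-values from 0.478 to 0.989. The median rate of helix 69 was 0.838%, 0.833%, 0.718% and 1.12%, and 1.19% at 0.5, 1, 1.5 (2 libraries) and 2.5 min. In helix 69 the largest slopes were at A1913, A1912 and C1914, with 0.195%, 0.439% and 0.838% at 0.5 min and 1.20%, 1.19% and 2.01% at 2.5 min (adjusted p = 0.999 for each by limma).

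Duplicate libraries were not the closest pairs. Over the 2164 sites, which are not independent replicates, log2 rates of the labelled mature libraries correlated with r = 0.812. The 1.5 min libraries, from different flow cells, correlated with r = 0.802, and those at 0.5 and 1 min with r = 0.958. Against the 1 unlabelled mature DMS library, which was assumed to vary like the other groups, 3 sites were called lower in labelled mature ribosomes (limma, 129 at an unadjusted p under 0.05). None was called without a variance trend or with the rate without DMS subtracted, although with that subtraction the log2 changes at 23S A309, 23S A191 and 16S A1502 were -2.65, -2.33 and -3.71, beside -2.29, -1.99 and -3.63. 23S A309 had 0.742% and 0.729% in labelled and 3.48% in unlabelled ribosomes (log2 change -2.29, SE 0.29, adjusted p = 0.00135). 23S A191 had 0.893% and 0.4% against 2.34% (adjusted p = 0.0314), and 16S A1502 was listed at 0 in both labelled libraries (adjusted p = 0.0176), which can be missing estimates. At these sites the unlabelled rates were near or within the nascent ranges of 1.80% to 8.66%, 2.18% to 4.33% and 0.935% to 2.40%. Labelling and flow cell changed together in this comparison.

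Some rRNA methylations block base pairing and are read as mutations without DMS, which allows their presence in nascent RNA to be followed. Without DMS, 16S m3U1498, made by RsmE, had 77.2% in unlabelled and 76.4% in labelled mature ribosomes, and 80.03%, 82.4% and 83.1% in nascent ribosomes at 0.5, 6.5 and 10.5 min. 23S m3Ψ1915 in helix 69, made by RlmH, had 84.5%, 89.1%, 90.5%, 89.1% and 92.5% in the same libraries. 23S m1G745 had between 81.0% and 85.2%. In DMS libraries m3U1498 had 73.8% ± 3.15 (SD, n = 2) in labelled mature ribosomes, 80.9% at 0.5 min and 70.5% at 1 min. It then had 50.7% ± 3.54 (n = 2) at 1.5 min and 50.7% at 2.5 min. m3Ψ1915 had 87.7% ± 0.298 (n = 2), 87.2%, 86.6%, 72.3% ± 1.05 (n = 2) and 59.0%.

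Over the chase times up to 2.5 min, 2 of the 12 face modifications were lower and 3 higher than in mature ribosomes, both adjusted over the list alone and over all 4446 positions. The lower ones were m3U1498 (log2 change -0.27, SE 0.05, adjusted p = 4.97e-07 over the list) and m3Ψ1915 (-0.21, SE 0.04, adjusted p = 5.89e-06). There was no library without DMS at 1, 1.5 or 2.5 min, so the DMS term came from the mature and 0.5 min groups alone. Whether these sites would also read lower without DMS at 1.5 and 2.5 min is therefore unknown, and the fall cannot be equated with less modification. Without the 2.5 min DMS library m3Ψ1915 had a log2 change of -0.09 and an adjusted p of 0.0891. m1G745 had 84.2% ± 1.28 and 75.2% ± 2.97 (n = 2 each) in mature and 1.5 min DMS libraries. Its adjusted p was 0.0942, and 0.00262 in the DMS libraries alone. Without the first 1.5 min library it was 0.00211, without the second 0.0179, and without the mature or the 0.5 min library lacking DMS 0.026 and 0.0213. The higher ones lay in helix 45: m2G1516 and m62A1518 were listed at 0 in both labelled mature DMS libraries and had 0.29% to 0.677% and 0.269% to 2.44% in nascent ones. m62A1519 had 1.28% ± 0.941 (n = 2) and 3.88% ± 0.544 (n = 2) at 1.5 min (log2 change 1.11, SE 0.34, adjusted p = 0.003), but without the second labelled mature DMS library its adjusted p was 0.674. DMS also reacts with A sites, and without DMS m62A1519 had 2.69% in labelled mature and between 2.43% and 2.73% in nascent ribosomes. In the unlabelled controls m62A1519 had 10.9% without and 12.7% with DMS, m2G1516 0.237% and 0.267%, and m62A1518 0.254% and 0.411%. The listings at 0 in labelled mature libraries can be missing estimates. Over all positions 1349 were higher and 8 lower, with a median log2 change of 0.82. For the 6.5 and 10.5 min libraries 2 of the 12 were higher (m2G1516, adjusted p = 0.00134, and m62A1518, 0.0033), over the list alone, and 0 over all positions (limma, 35 positions at an unadjusted p under 0.05). Both were listed at 0 in all labelled mature libraries, and m62A1518 had 1.51% at 6.5 min and was listed at 0 at 10.5 min. The other 6 modifications, m2G966, m2G1207, m4Cm1402, m2G1835, m2G2445 and m2A2503, did not pass (adjusted p from 0.192 to 0.413). Their 1.5 min means lay between 0.42% (m2A2503) and 4.58% (m2G1207), against 0.308% and 3.63% in mature ribosomes.

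**Figure D4:**
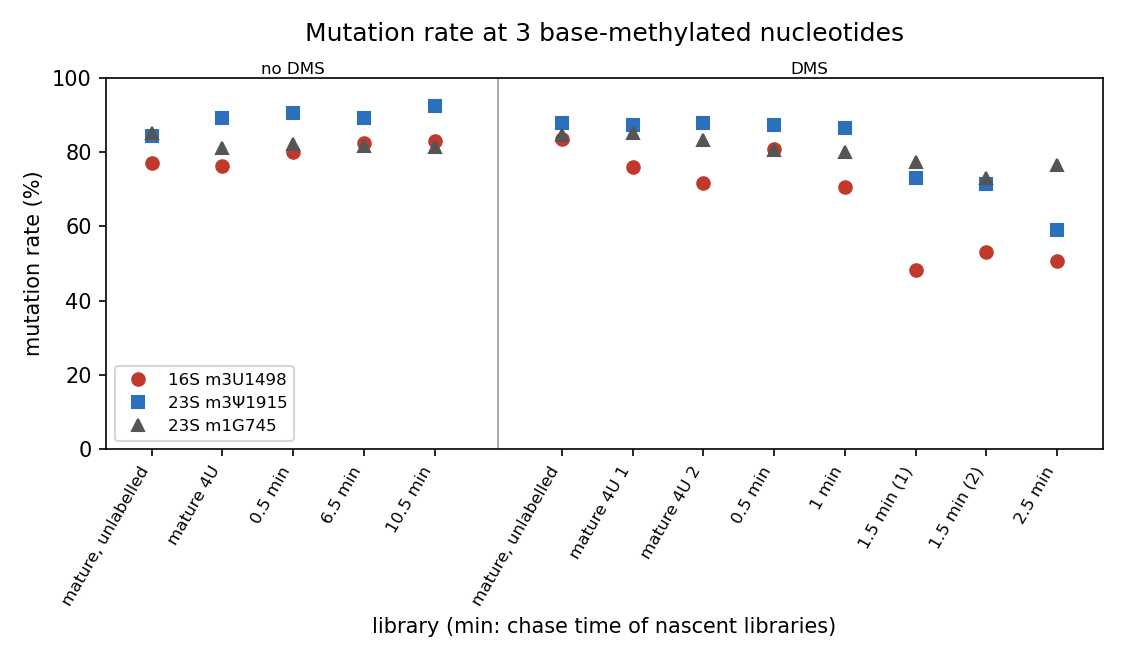
Mutation rate (%, y axis) at 16S m3U1498, 23S m3Ψ1915 and 23S m1G745 in each of the 13 libraries (x axis), without DMS on the left and with DMS on the right; each point is a library. The 1.5 and 2.5 min DMS libraries have between 48.2% and 53.2% at m3U1498 and between 59.0% and 73.0% at m3Ψ1915.

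Leader and trailer segments, which are removed during processing of the precursor, carried values in the unlabelled libraries and, among the labelled ones, mainly in the nascent DMS libraries from 1 min on. In the 16S leader (147 positions) 6.12% of positions were listed at 0 at 1 min, 19.0% and 16.3% at 1.5 min and 24.5% at 2.5 min. At 0.5 min the share was 53.1%, in labelled mature DMS libraries 88.4% and 74.1%, and in the unlabelled ones 27.9% without and 18.4% with DMS. The 23S leader (122 positions) had 75.4% at 0.5 min, 12.3% at 1 min, 18.03% and 4.92% at 1.5 min, 18.9% at 2.5 min and 95.1% and 87.7% in mature ribosomes. Median A and C rates of the 16S leader were 1.22%, 1.41%, 1.50%, 1.77% and 1.19% at 0.5, 1, 1.5 (2 libraries) and 2.5 min. The unlabelled mature DMS library had 0.968%, and the libraries without DMS had at most 0.0501%. Over values above 0 the medians were 1.45% to 2.69% in nascent DMS libraries and 0.0854% to 1.82% without DMS. The share of listings at 0 depends on depth, which is unknown.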

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

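The tests of explanations in this part were chosen only after the result was seen, and the splits of the libraries were planned but their expected outcome was written down afterwards.

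Unmodified U positions, which were left out of the comparisons of A and C sites, stood above the libraries without DMS: the lowest median among the 5 nascent DMS libraries was 0.43%, against at most 0.203% without DMS. A background of the size of the rise at U was set against the rise at closed sites, first over the 5 libraries together, which left it undecided, and then at each chase time. At closed A sites the rise exceeded that at U by 0.479, 0.237 and -0.00507 percentage points at 0.5, 1 and 2.5 min. In the 1.5 min libraries it did so by 0.308 and 0.892. At closed C sites the excess was 0.306 and 0.207 at 0.5 and 1 min. It was at most -0.0693 at 1.5 min and -0.0562 at 2.5 min. The cut-off was the difference between the mature libraries, 0.00177 points for A and 0.0271 for C. Such a background may therefore account for the rise at 2.5 min and, for C, at 1.5 min. For A at 1.5 min both libraries argue against it. At 0.5 and 1 min it stays undecided, since each has 1 library and the 1.5 min libraries lay far apart. A background that differs between bases stays open, since G rose by 0.912 and 0.704 points at 0.5 and 1 min, more than closed A sites (0.732 and 0.504, differences down to -0.1998), and by 0.836 beside 0.783 at 2.5 min, whereas at 1.5 min G changed by 0.34 and -0.0705 and closed A sites by 0.725 and 1.24. Mutations at 4-thiouridine itself without DMS, as the source of this rise, were argued against by a difference of 0.00252 points between the median U rates of the 0.5 min and the labelled mature library without DMS, but a share common to all labelled libraries (0.153% to 0.203% without DMS, against 0.0751% unlabelled, with another flow cell), a reaction of 4-thiouridine with DMS or a different depth stays open.

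The larger change of closed than of open sites is a further pattern that such a background could shape, since it weighs more on low rates in log units. With the median U rate subtracted and no scaling, the difference between closed and open sites was 0.27, and the open class was not called (adjusted p = 0.313). With the subtraction and scaling it was 0.46 and called (adjusted p = 4.88e-06), beside 0.89 as reported, while with the subtraction, no scaling and a pseudocount of 0.01 it was -0.05. More exposure of protected sites in unfinished particles and a background therefore cannot be told apart here. The outcome turns on the scaling and on the pseudocount, which these libraries do not settle. A pseudocount of 0.01 equals the upper limit of the closed class (1%) and so shrinks log2 changes at closed sites. The value of -0.05 therefore does not decide between the 2 explanations.

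The lower rates of m3U1498 and m3Ψ1915 in the 1.5 and 2.5 min DMS libraries (logit changes -1.01 and -1.22 against mature ribosomes) were set against a general fall at high rates. Of 26 unmodified sites with over 5% in every library without DMS, 22 were lower. Their median logit change was -0.106 and the lowest -0.415. This argues against an equal fall at every high site, although none of them exceeded 43.6% in mature ribosomes. Since these sites read high without a listed modification, they cannot show whether the reading of methylated bases changed in general. A fall at rates above 60% stays open, since 16S A915 (68.1%) and 23S m1G745 (84.2%), the other sites in that range, changed by -0.61 and -0.54. Modification that is less complete the shorter the chase was argued against by mean changes from mature ribosomes. At 0.5 and 1 min these lay at least 19.8 percentage points above those at 1.5 and 2.5 min. The short-chase means included the 0.5 min library without DMS, set against the labelled mature library without DMS. In DMS libraries alone m3Ψ1915 had 87.2% and 86.6% at 0.5 and 1 min, and 73.0%, 71.5% and 59.0% at 1.5 (2 libraries) and 2.5 min. At m3U1498 these were 80.9% and 70.5%, and 48.2%, 53.2% and 50.7%. Mature RNA carried over in the shortest chases may hide less complete modification there. In the 1 min library 12.3% of 23S leader positions were listed at 0, against 75.4% at 0.5 min, but since depth is unknown the share does not decide it.

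The response of A and C sites to DMS was set against other splits of the 13 libraries into 8 and 5. Of 100 splits, 1, the real one, called as many sites (1945), and the highest of the others called 1, so chance can be excluded for that count.

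The 16S leader had higher medians in nascent DMS libraries than without DMS, but listings at 0, which can be missing estimates, weigh on that difference. The lowest median A and C rate of the 16S leader among nascent DMS libraries was 1.19%, against at most 0.0501% without DMS. Over values above 0 the medians were 1.45% to 2.69% in nascent DMS libraries, 0.0854% in the unlabelled library without DMS and 0.366% to 1.82% in the labelled ones without DMS. The spacer between 23S and 5S rRNA had a median A and C rate of 1.51% in the second 1.5 min library, which came from a flow cell of its own. The median was 0% in the other nascent DMS libraries and in those without DMS, where 75.3% to 91.4% and 87.1% to 97.8% of positions were listed at 0.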

How the results depend on the processing

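Subtraction of the median U rate, leaving out sites listed at 0, and, for closed and open sites, all but no scaling and other thresholds were chosen after seeing the data. The response to DMS (1398 to 1924 sites over the settings, 1746 to 2050 with a library left out) was within 1.5 times its count throughout. Depth is unknown and limits every rate. With either 1.5 min library out, only the mature pair sets the spread. No paired analysis was possible because no groups share replicate numbers that pair them: the labelled mature DMS libraries carry 1 and 2, one 1.5 min library carries none and the other, with 2, is from another flow cell, and the numbers of nascent libraries without DMS go with chase times. The causes of the changes below were not tested, except that fewer sites or libraries can leave fewer calls.

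For nascent against mature, 397 higher and 25 lower sites became 252 higher with a pseudocount of 0.0001, 1637 and 3 without scaling, 37 and 123 with median centring, 95 and 0 without a variance trend, and 121 and 11 with the unlabelled library among the mature ones. Lower sites numbered 38 without the filter on rates without DMS and 14 with the rate of the labelled mature library without DMS subtracted. A sites alone gave 631 higher, C sites alone 1 and 0 lower, and flow cell B alone 14 and 3. The median U rate was subtracted in 6 ways: with and without scaling, both again with a pseudocount of 0.01, the last of these also without the second 1.5 min library, and with scaling, that pseudocount and sites of at least 1% mean rate. The first 5 gave 0 higher and 0 lower, and the last 22 and 4 of 878 sites. With a library left out, 14 to 419 were higher and 3 to 26 lower. Sites called at any chase time (363) became 196 with the smaller pseudocount, 1554 without scaling, 160 with centring, 100 without the trend, 3 with the rate without DMS subtracted, 0 with U subtracted in the first 5 ways and 39 in the last. Change with chase time gave 2 sites, in place of 0, with the rate without DMS subtracted, and 0 with any library left out. Labelled against unlabelled mature ribosomes (3) gave 5 with a pseudocount of 0.01 or without zeros, 11 without scaling, 6 without the filter, 0 without the trend or with the rate without DMS subtracted, 0 with U subtracted in the first 5 ways and 1 in the last.

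Lists called for nascent against mature (1) became 0 with an estimated correlation, centring or U subtracted with scaling, 2 without zeros, 3 with U subtracted in the last way, and 1 to 2 with a library left out, where the 1 without the first labelled mature library was another list (the 3' tail had an adjusted p of 0.977). Those over chase time (2) became 0 with an estimated correlation, 0 with U subtracted in 5 of the ways and 1 in the way without the second 1.5 min library, and 0 to 2 with a library left out. Closed minus open sites (0.89) was 0.27 and not called with U subtracted and no scaling, turned to -0.0501 with the pseudocount of 0.01 as well and to -0.0364 without the second 1.5 min library on top, and was 0.86 to 0.94 with a library left out. Modified sites numbered 1 to 3 lower and 2 to 3 higher with a library left out, with 1 lower without the 2.5 min DMS library. Direction turned at 23S A340 (0.57) and 23S A1640 (0.12) without scaling, at 23S A1640 with U subtracted and no scaling (0.086, 0.082 with the pseudocount of 0.01 and 0.097 without the second 1.5 min library), and at 16S A1542, which had -1.29 without the second and 4.04 without the first labelled mature library. For called single sites and lists, 450 of 796 alternatives kept the call and direction, 342 ended the call and 4 turned the direction. For those not called, 157 of 171 stayed so, 10 of them with the other sign, and 12 and 2 were called in the same and the other direction. Counts per chase time were within 1.5 times in 12 of 60 alternatives, lower in 37 and higher in 11.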

Other observations

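Apart from the listed modifications, 26 positions of 16S and 23S rRNA had over 5% mutations in every library without DMS. Several lay close together at similar rates: 16S G79 and C90 had 27.1% and 27.7% in unlabelled mature ribosomes without DMS, 23S C1513 and C1518 had 9.001% and 8.88%, and 23S A1220 and U1229 had 7.68% and 7.90%. The highest were 16S C183 (41.3%) and 23S C164 (42.9%). In the 2.5 min DMS library these last 2 sites had 37.9% and 30.6%.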
